A study of Mus musculus with 16 samples.

How the data were processed

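RNA of a pair of mouse CD8 T cell clones was hybridised to Affymetrix whole-transcript arrays. Per the labels, the conventional clone is a cyclosporine-sensitive CD8 T cell and the unconventional clone a cyclosporine-resistant one. Both were activated with immobilized antibody to CD3, a chain of the T cell receptor complex, in medium without recombinant cytokines, with or without cyclosporine A at 1 ug per ml. Cyclosporine A binds cyclophilin A, and the complex inhibits the phosphatase calcineurin, which activates NFAT transcription factors. The clones had been grown with a mixture of cytokines, per the labels' protocols. There were 4 arrays in each of 4 groups, 16 in all, and each comparison below is between groups of activated cells, since unstimulated cells were not analysed here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

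The values are log2 expression values per probe set, as deposited by the authors. Per the submitters' processing notes, GCOS, Partek 6.2 and RMA were used, with no role or order given. RMA corrects background, quantile-normalizes arrays and summarises probes, which makes arrays comparable in distribution and would hide a change shared by most transcripts. The log2 scale was inferred from the values, which ran from 2.08 to 14.55. The medians of the 16 arrays lay between 5.16 and 5.35, and arrays of one group correlated at 0.995 to 0.998 over probe sets, with no identical pair. The genome build and the annotation version used by the authors are not given in the sources used here. Arrays give no counts, so their number limits the precision. Values near the lower end are background, where RMA compresses differences, and a fold against such a level is in general smaller than the change in RNA.

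Of 28853 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 5443 had none here. An Entrez ID of the gene table of assembly GRCm38.p6 matched 99.6% of the probe sets with 1 symbol, and 0 symbols changed on update. For the 999 genes with several probe sets, the one with the highest mean over all arrays was used, which left 19938 genes. No gene was named from a probe set with several symbols. No filter on dim genes was applied in the reported results.

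A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with empirical Bayes moderation of the variance, 12 residual degrees of freedom and a median of 18.8 after moderation. The contrasts were cyclosporine A against none in each clone, the difference of these effects between the clones, and the clones against each other with anti-CD3 alone and with cyclosporine A. All tests were two-sided. P-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Counts of called genes that also changed at least 2-fold are given beside them. The share of effect is the log2 change in the unconventional clone divided by that in the conventional clone, over genes called and changed at least 2-fold in the conventional clone, given as a median with a 95% interval from 10000 bootstrap draws of genes. Genes picked for a large change in one clone tend to look smaller in the other, so the reverse share was computed too.

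Before the data were examined, 27 gene lists naming 566 genes, the contrasts, the alternatives and the rule for named genes were fixed. Of these genes, 519 were measured. The lists were effector cytokines, chemokines, TNF superfamily ligands, activation and inhibitory receptors, EGR, NR4A and anergy genes, AP-1, MAPK feedback and immediate early genes, NF-kB pathway and targets, cytotoxic granule genes, NK cell receptors and adaptors, T cell transcription factors, trafficking and adhesion, T cell receptor signalling, calcium, calcineurin and NFAT, cell cycle, glycolysis and hypoxia, sterol synthesis, the unfolded protein and amino acid stress response, interferon-stimulated genes, cytokine receptors with SOCS and PIM genes, apoptosis and p53, naive and memory T cell genes, markers of B cells, of macrophages and dendritic cells, of epithelium and fibroblasts, of erythroid cells and granulocytes, and of other T cells, and reference genes. Each list was tested with camera at a preset correlation of 0.01, with adjustment over the 27 lists of a contrast, and again with the correlation estimated and with fry. The named genes were the 10 with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap between groups (called genes only for the difference of effects), 5 and 5 for the clones with cyclosporine A, up to 4 members of each list with the largest absolute change, and 12 genes in every contrast. Receptor and immunoglobulin segments were kept out of the largest changes.

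The steps were tested on simulated data made from the real means and residual spreads, with noise drawn independently for each gene. For the conventional clone's cyclosporine A contrast, run on 19938 genes with 200 changed, the calls recovered 87.9% of genes changed by 0.5 on the log2 scale and 100.0% of those changed by 1 or 2, and 5.4% of the calls were false. For the difference of effects, also on 19938 genes with 200 changed, the shares were 40.3% at 0.5 and 94.5% at 1, with 5.6% of calls false. Real genes are correlated and many more of them were called, so these shares check the steps and do not carry over to the results. The alternatives were a replicate block, fits on the arrays of 2 groups, other settings of the variance moderation, a filter that kept the brighter genes alone (a mean over all arrays above the median), other normalizations between arrays, all probe sets, array weights, each array left out in turn and other thresholds.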

Results

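The series measured gene expression on 16 arrays from a conventional and an unconventional mouse CD8 T cell clone, each activated through CD3 with or without cyclosporine A, with 4 arrays per group. The labels describe the conventional clone as sensitive to the drug and the unconventional clone as resistant to it. Levels are log2 expression values given as mean ± SD with n = 4, and changes are differences of log2 values with their standard error (SE). The identity of the clones was visible in the receptor: the β-chain segment Trbv1 stood at 13.14 ± 0.02 (SD, n = 4) in the conventional clone with anti-CD3 alone and at 4.66 ± 0.22 (SD, n = 4) in the unconventional clone. Cd8a and Cd8b1, the chains of the CD8 co-receptor, were well expressed in both, while Cd4 lay between 4.21 and 4.32 in all groups.

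The first comparison asked what cyclosporine A changed in activated cells of the conventional clone. Cytokine and chemokine genes were among those that fell furthest. Il24, a cytokine of the IL-10 family, fell from 12.84 ± 0.06 to 4.14 ± 0.26 (SD, n = 4), a change of -8.70 (SE 0.11, adjusted p = 1.1e-20). The anti-inflammatory cytokine Il10 changed by -6.31 (SE 0.19), the chemokine Ccl3 by -6.26 (SE 0.21), and Ifng, the main effector cytokine of CD8 T cells, by -3.43 (SE 0.11), with a level of 10.55 ± 0.10 (SD, n = 4) left under the drug. Genes of DNA replication and mitosis fell with them, and sterol synthesis genes rose (adjusted p = 0.0196 and adjusted p = 0.1836 with an estimated correlation). The drug's own target, cyclophilin A (Ppia), was at 13.64 and 13.61 without and with it and was not called.

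In this clone 6269 of 19938 genes were called (31.4%), 3179 higher and 3090 lower with the drug. At least 2-fold changes numbered 473 rises and 536 falls. The arrays of both groups did not overlap for 6073 of all 19938 genes, against a chance share of 2.86%. Of the called genes, picked on the same arrays, 5529 did not overlap. Besides Il24, Il10 and Ccl3, the largest falls were in Olfm4 (-6.71), Lum (-5.71), AI504432 (-5.32), the chemokines Ccl9 (-4.78) and Xcl1 (-4.61), Akr1c18 (-4.60), which inactivates progesterone, and Il1a (-4.37). The largest rises were in Pfpl, a perforin-like gene, from 4.23 to 9.78 (5.54), Arhgap42 (5.15), Osgin1 (3.45), the acetyl-CoA synthetase Acss2 (3.23), the fatty acid transporter Slc27a1 (3.22), Hsd11b1 (3.22), which activates glucocorticoids, Igsf5 (3.18), the phosphatase Ubash3b (3.18), a negative regulator of receptor signalling, Tmem40 (2.96) and Eya2 (2.88). A dimmer second probe set of Arhgap42, with a mean level of 3.87, changed by -0.02.

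Among the effector cytokines, 13 of 20 measured genes fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 2.5e-08). The T cell growth factor Il2 fell from 5.69 to 4.39, Tnf changed by -0.95, Csf2 by -0.74 and Lta by -3.96. Of 14 chemokines, 10 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 5.3e-08), among them Ccl5 at -2.35. Cell cycle genes gave the lowest p of the lists: 29 of 30 fell, 23 of them at least 2-fold (29 adjusted over the list alone; camera adjusted p = 1.4e-28, median -1.54). The cyclins Ccne2 and Ccna2 changed by -3.57 (SE 0.17) and -3.51 (SE 0.16), the replicative helicase subunit Mcm7 by -2.93 and the mitotic kinase Cdk1 by -2.85. These were the 3 list calls in this clone that held with an estimated correlation, each at an adjusted p of 0.0196.

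Sterol synthesis genes moved the other way, with 14 of 15 higher and 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 9.0e-08, and adjusted p = 0.1836 with an estimated correlation). Hmgcs1, which makes HMG-CoA, rose by 1.48, the lanosterol synthase Lss by 1.22, Msmo1 by 1.14 and Fdft1 by 1.09. NF-kB pathway genes mostly fell, 14 of 19 against 2 rises (14 and 2 adjusted over the list alone; camera adjusted p = 9.5e-06, and adjusted p = 0.1377 with an estimated correlation). The survival gene Bcl2l1 led the falls at -2.97, while Nfkbiz and Cyld rose by 1.66 and 1.23. Of 26 cytokine receptor, SOCS and PIM genes, 13 fell and 3 rose (14 and 5 adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.1377 with an estimated correlation), with Socs3, a feedback inhibitor of cytokine signalling, at -3.18. Glycolysis and hypoxia genes included 9 falls and 0 rises among 19 (10 and 0 adjusted over the list alone; camera adjusted p = 0.0084, and adjusted p = 0.6116 with an estimated correlation), with Hif1a at -1.42 and the hexokinase Hk2 at -1.27. That call was lost among the brighter genes alone, where the list kept all 19 members and its median of -0.20 but was set against fewer other genes.

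Receptor signalling genes were called upward, with 16 of 30 higher and 6 lower (16 and 6 adjusted over the list alone; camera adjusted p = 0.0046, and adjusted p = 0.1605 with an estimated correlation). The kinase Fyn rose by 1.76 and the adaptor Pag1 by 1.52, while the kinase Prkcq changed by -2.80. Trafficking genes included 11 rises and 4 falls among 24 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.0582 with an estimated correlation). The integrins Itga2 and Itgb3 rose by 2.37 and 2.17, and the chemokine receptors Ccr4 and Ccr7 changed by -3.22 and -3.10. Stress response genes rose in 12 of 23 cases and fell in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0046, and adjusted p = 0.4180 with an estimated correlation), including Trib3 (1.58) and Ddit3 (1.12).

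The other 17 lists were not called in the conventional clone, although single members changed. The inhibitory receptors Ctla4 and Tigit changed by -4.01 and -2.56 and the co-stimulatory receptor Cd28 by 1.73 (activation receptors, 3 rose and 8 fell of 21, and 3 and 8 adjusted over the list alone; camera adjusted p = 0.0623). Nr4a3 changed by -1.51 in the EGR and NR4A list (3 rose and 7 fell of 18, and 3 and 7 adjusted over the list alone; camera adjusted p = 0.4701), the AP-1 family gene Batf3 by -3.42 and the phosphatase Dusp1 by 2.01 in the AP-1 list (8 rose and 10 fell of 26, and 8 and 10 adjusted over the list alone; camera adjusted p = 0.7361), and the OX40 ligand Tnfsf4 by -3.49 among TNF ligands (2 rose and 4 fell of 11, and 2 and 4 adjusted over the list alone; camera adjusted p = 0.6188). Of 21 cytotoxic granule genes, 9 rose and 7 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.9510), and of 23 NK cell receptor genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.9510). T cell transcription factors included 6 rises and 6 falls among 24 (6 and 7 adjusted over the list alone; camera adjusted p = 0.7909), and calcium, calcineurin and NFAT genes 7 rises and 9 falls among 28 (8 and 10 adjusted over the list alone; camera adjusted p = 0.8712). Interferon-stimulated genes rose in 4 and fell in 8 of 25 cases (4 and 8 adjusted over the list alone; camera adjusted p = 0.2511), apoptosis genes in 6 and 9 of 22 (7 and 10 adjusted over the list alone; camera adjusted p = 0.0623) and naive and memory genes in 3 and 6 of 17 (3 and 6 adjusted over the list alone; camera adjusted p = 0.2511). The NFAT target Rcan1 (-0.13, adjusted p = 0.3895) and Egr2 (0.12, adjusted p = 0.3923) were not called, whereas Nfatc1 changed by -0.36 and Nr4a1 by -0.55.

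Markers of other cells and reference genes served as background. Of 9 B cell and 12 erythroid and granulocyte markers, 0 were called in the conventional clone, over all genes or adjusted over the list alone (camera adjusted p = 0.8712 and 0.8225). Of 10 markers of other T cells, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.8712), and of 20 macrophage and dendritic cell markers 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.7492), with Itgax at 1.33 and Cd68 at 0.79. Of 16 epithelial and fibroblast markers, 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.7909), among them Lum, whose level with anti-CD3 alone was 9.87 ± 0.26 (SD, n = 4). Of 14 reference genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.7361). Over all contrasts, 38 of 135 list tests were called, and in each called list the median, mean and test had the same sign. Signs differed in 23 of the 97 not called, such as the TNF ligands above, with a median of 0.01 and a mean of -0.22.

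The second comparison asked the same of the unconventional clone, labelled resistant. Its effector cytokine genes fell too. Il24 went from 13.18 ± 0.16 to 4.13 ± 0.17 (SD, n = 4; -9.05, SE 0.11), a background level as in the conventional clone with the drug, so the fall is a lower limit in both. Ccl3 changed by -7.55 (SE 0.21), and Ifng by -5.28 (SE 0.11, adjusted p = 2.8e-17), from 13.21 ± 0.09 to 7.93 ± 0.31 (SD, n = 4). Cell cycle genes fell by less (adjusted p = 0.0950 with an estimated correlation for the difference of effects), and sterol synthesis genes were not called as a list.

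Here 4970 genes were called (24.9%), 2518 higher and 2452 lower, with 245 rises and 213 falls of at least 2-fold. With median centring the split was 1931 higher and 2684 lower. Arrays did not overlap for 5427 of all genes, against a chance share of 2.86%, and for 4467 of the called genes, picked on the same arrays. The largest falls also included Akr1c18 (-5.85), Xcl1 (-5.18), Olfm4 (-4.49), Il10 (-4.47), Tm4sf1 (-4.14), the growth factor Igf1 (-4.13) and Tnfrsf11b (-3.87), a decoy receptor for RANK ligand. The largest rises were in Arhgap42 (3.56), the imprinted gene Mest (3.34), the p53 target Trp53inp1 (3.32), the collagen gene Col6a3 (3.31), Klhl30 (3.22), the receptor Vipr2 (2.71), Padi2 (2.70), the NK receptor chain Klrd1 (2.69), the checkpoint gene Vsir (2.64) and Rasgrp3 (2.50), an activator of Ras.

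Of 20 effector cytokines, 12 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 9.3e-15). Il17a changed by -3.47, Il2 by -1.97, Tnf by -1.34 and Csf2 by -0.72. Chemokines fell in 6 of 14 cases (6 adjusted over the list alone; camera adjusted p = 3.0e-06), with Cxcl2 at -3.29 and Ccl4 at -3.14. Of 30 cell cycle genes, 27 fell but 1 did so by at least 2-fold (28 adjusted over the list alone; camera adjusted p = 8.4e-16, median -0.64). Cdk1 changed by -1.03 (SE 0.12) and Ccne2 by -0.89 (SE 0.17). Apoptosis genes included 11 falls and 6 rises among 22 (12 and 6 adjusted over the list alone; camera adjusted p = 0.0014), with Gadd45g at -2.63, Bcl2l1 at -2.14 and Bcl2 at -2.05. T cell transcription factors were the list called upward, with 11 of 24 higher and 3 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.0049), among them Ahr (1.53) and Bcl6 (1.29). These 5 calls held with an estimated correlation, at adjusted p = 0.0045 for cytokines, 0.0412 for chemokines, apoptosis genes and transcription factors, and 0.0469 for cell cycle genes.

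A further 6 lists were called downward but lost their call with an estimated correlation. NF-kB genes fell in 13 of 19 cases and rose in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.1009 with an estimated correlation). Activation receptors fell in 12 of 21 and rose in 5 (12 and 5 adjusted over the list alone; adjusted p = 0.1015 with an estimated correlation). Cytokine receptor, SOCS and PIM genes fell in 12 of 26 and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.1015 with an estimated correlation), with the feedback inhibitor Cish at -2.07. The AP-1 list had 13 falls and 4 rises among 26 (13 and 4 adjusted over the list alone; adjusted p = 0.1873 with an estimated correlation). Naive and memory genes had 6 falls and 2 rises among 17 (7 and 2 adjusted over the list alone; adjusted p = 0.1873 with an estimated correlation) and glycolysis genes 4 falls and 1 rise among 19 (5 and 1 adjusted over the list alone; adjusted p = 0.6839 with an estimated correlation). The glycolysis call was lost without unconventional anti-CD3 replicate 4 (median -0.10), or without replicate 2 (-0.09) or 3 (-0.16) with the drug, among the brighter genes alone (-0.15, as among all genes), and after quantile (-0.13) or cyclic loess (-0.16) normalization. Of 15 sterol synthesis genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.1157), with Hmgcs1 at 1.03 and Sqle at -0.65. Cd8a fell by 1.75, while Cd8b1 (0.03) and Rcan1 (0.12) were not called.

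The third comparison set the drug's effects in both clones against each other. Much of the response was shared in direction. Genes picked for a large change in either clone tended to change less in the other. Ifng fell by 1.85 more in the unconventional clone (-1.85, SE 0.16, adjusted p = 5.9e-08), whereas Ccna2 fell less there (2.69, SE 0.22, adjusted p = 4.4e-08). The comparisons in the 2 clones share no arrays, but they use the same variance per gene, pooled over all groups. Genes lower in both numbered 1686, against 380.0 for independent calls over all 19938 genes, and genes higher in both 1557 against 401.5. Opposite directions were seen for 111 and 112 genes, against 390.2 and 391.0. The shared variance, and dim genes that are rarely called in either clone, tend to make these expected numbers too low. The excess of shared calls is therefore overstated, while the opposite calls lay below their expected numbers even so. The log2 changes correlated across genes at r = 0.631 (Spearman's rho 0.510), and genes are not independent replicates.

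**Figure D1:**
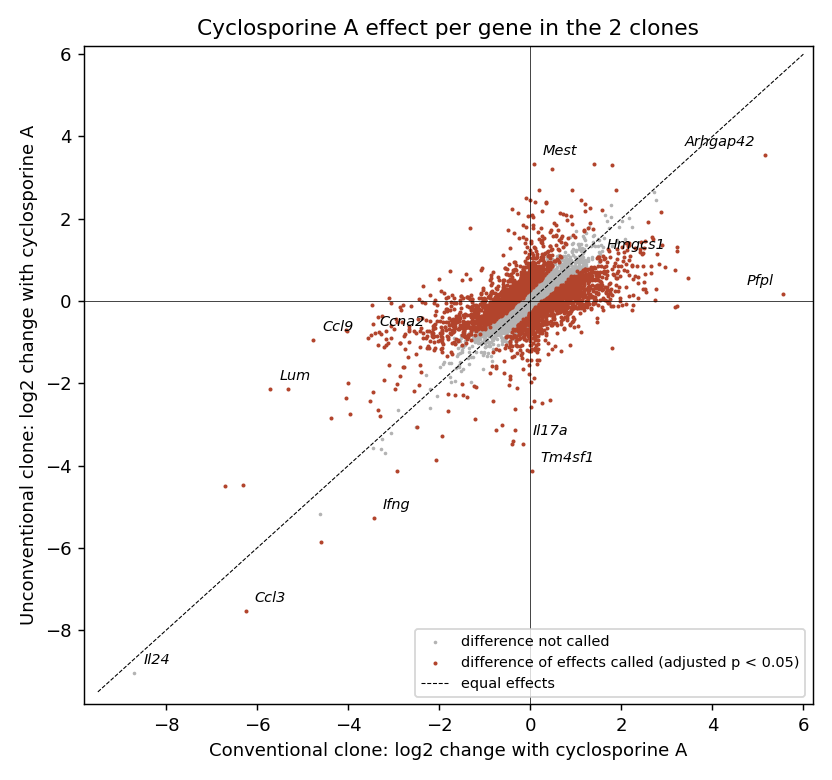
Log2 change with cyclosporine A in the conventional clone (x axis) and in the unconventional clone (y axis), 1 point per gene, with 4 arrays per group. Coloured points are the 3247 genes whose effect differed between the clones, the dashed line marks equal effects, and Ifng lies below it at -3.43 and -5.28.

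The difference of effects was called for 3247 genes (16.3%), 1696 with a higher value in the unconventional clone and 1551 with a lower one, and it was at least 2-fold for 330 and 292 of them. Of 536 genes that fell at least 2-fold in the conventional clone, 423 were also called lower in the unconventional clone, 9 were called higher and 104 were not called. The effect was called smaller there for 397 and larger for 16. Of 473 that rose, 353 were called higher too, and the effect was smaller for 358 and larger for 13. The difference was computed from the same arrays that picked these genes. Among 213 genes picked by a 2-fold fall in the unconventional clone, the effect in the conventional clone was smaller for 92 and larger for 50. For 245 genes picked there by a 2-fold rise, it was smaller for 114 and larger for 39.

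The median share of the conventional clone's effect found in the unconventional clone was 0.425 (95% interval 0.405 to 0.444, 1009 genes), and 91.0% of these genes kept their sign. Picked in the unconventional clone instead, the reverse share was 0.726 (0.662 to 0.803, 458 genes). For 8 effector cytokine genes the share was 0.874 (0.301 to 1.523), for 23 cell cycle genes 0.313 (0.253 to 0.369) and for 6 sterol synthesis genes 0.035 (-0.122 to 0.581). The cytokine genes kept a larger share than the cell cycle genes, by 0.561 (permutation p = 6.8e-04, a test across genes).

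**Figure D2:**
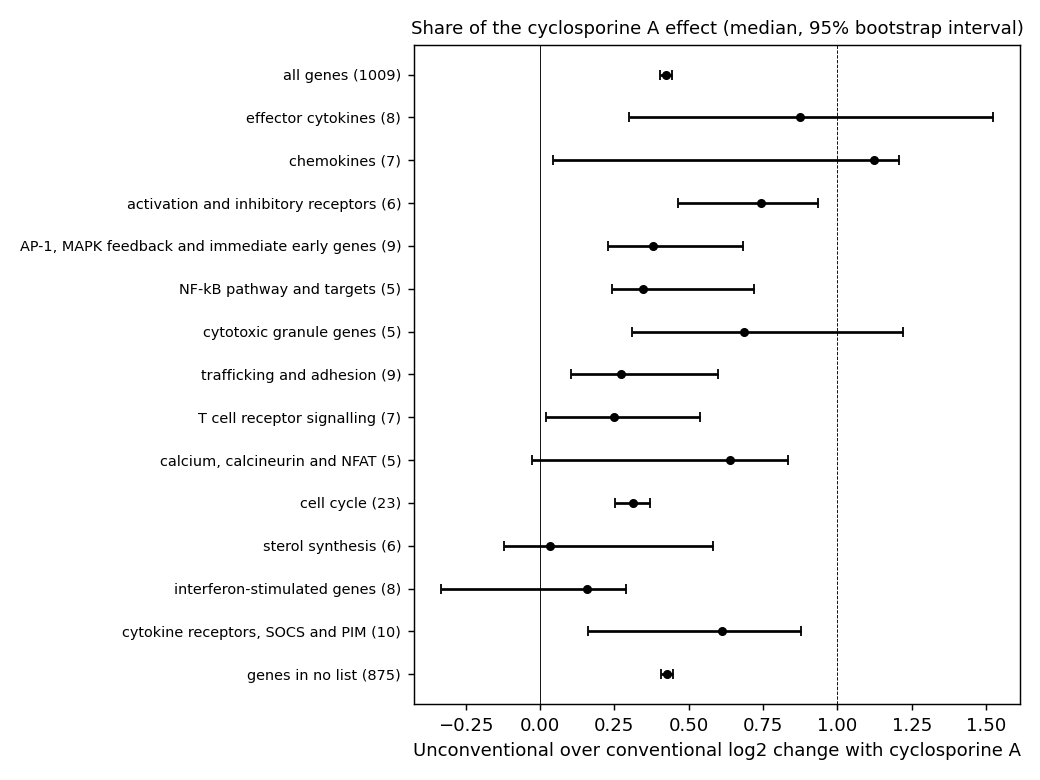
Median share of the conventional clone's cyclosporine A effect found in the unconventional clone (x axis, ratio of log2 changes), for all genes picked in the conventional clone and for lists with at least 5 of them (number of genes in parentheses), with 95% bootstrap intervals. The share was 0.425 over all 1009 genes and 0.313 for cell cycle genes, and the dashed line marks equal effects.

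Cell cycle genes differed most as a list, with 21 of 30 falling less in the unconventional clone and 0 falling more (23 and 0 adjusted over the list alone; camera adjusted p = 4.6e-21, median 1.13, and adjusted p = 0.0950 with an estimated correlation). Besides Ccna2, they included Ccne2 (2.67), Mcm7 (2.41) and the replication licensing gene Cdc6 (1.98). Sterol synthesis genes had a lower effect in the unconventional clone in 14 of 15 cases (14 adjusted over the list alone; camera adjusted p = 9.7e-14, and adjusted p = 0.1155 with an estimated correlation), such as Cyp51 (-1.43) and Lss (-1.32). The stress response list was lower in 12 of 23 cases and higher in 0 (14 and 1 adjusted over the list alone; camera adjusted p = 8.4e-07, and adjusted p = 0.1415 with an estimated correlation), with Trib3 at -1.73. T cell receptor signalling genes were lower in 13 of 30 and higher in 5 (16 and 6 adjusted over the list alone; camera adjusted p = 0.0083, and adjusted p = 0.1605 with an estimated correlation), among them Fyn (-1.32). Interferon-stimulated genes were higher in 10 of 25 and lower in 3 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0095, and adjusted p = 0.1302 with an estimated correlation), with the transcription factors Irf1 (2.07) and Irf7 (2.01). T cell transcription factors were higher in 8 of 24 and lower in 3 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0186, and adjusted p = 0.1068 with an estimated correlation), with Ahr (1.77) and Prdm1 (1.30) higher and Gata3 (-1.42) lower. The transcription factor call was also lost among the brighter genes alone (median 0.10). Of the 6 list calls in this comparison, 0 held with an estimated correlation.

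**Figure D3:**
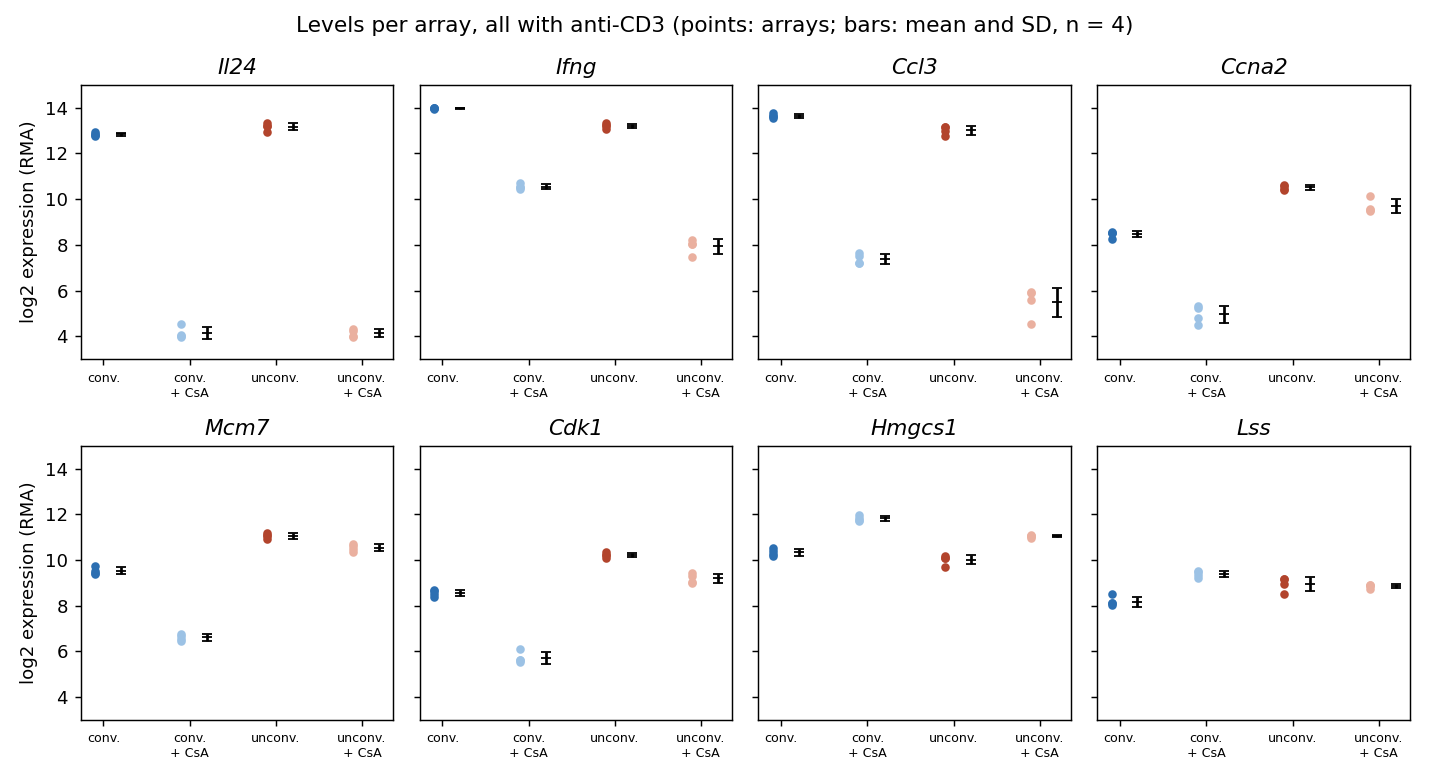
Log2 expression (y axis) of 8 genes on each array of the conventional (conv.) and unconventional (unconv.) clone with anti-CD3, without and with cyclosporine A (CsA). Points are arrays and bars mean and SD (n = 4), and with the drug Ccna2 stood at 4.96 in the conventional and 9.69 in the unconventional clone.

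Effector cytokines were not called as a list (camera adjusted p = 0.3211), with 5 higher and 4 lower of 20 (5 and 6 adjusted over the list alone). Il17a, Il3 and Il17f had lower effects in the unconventional clone (-3.32, -3.03 and -2.79), where they were expressed with anti-CD3 alone, at 8.46, 6.98 and 7.92. Il9 fell less there (2.25), from 5.95 with anti-CD3 alone against 8.48 in the conventional clone. Il10 (1.84, SE 0.27) and Lta (1.21, SE 0.19), picked for this comparison after their values were seen, also fell less there. The differences for Il2 (-0.68, adjusted p = 0.0759), Tnf (-0.39, adjusted p = 0.0871) and Csf2 (0.03, adjusted p = 0.9658) were not called. Without unconventional anti-CD3 replicate 1, those for Il2 (-0.90) and Tnf (-0.53) were called. Both were also called with array quality weights (-0.77 and -0.485), and that for Il2 with the replicate block (-0.68). That for Tnf was called with trend and robust settings of the variance moderation (-0.39). The lowest single differences also included Pfpl (-5.38), Tm4sf1 (-4.16), Hsd11b1 (-3.34), Ubash3b (-3.32), the keratin gene Krt23 (-3.07), Csta3 (-2.93), Osgin1 (-2.89) and Gm5486 (-2.84), whose dimmer second probe set gave -0.13. The highest were Ccl9 (3.83), Lum (3.58), Tnfsf4 (3.38), Ambn (3.34), Acpp (3.31), Mest (3.26), AI504432 (3.18), Fat1 (3.17), Xylt1 (3.08) and Ifi205 (3.00). Tnfsf4 fell from 7.55 to 4.07 in the conventional clone and was at 4.47 and 4.37 in the other, near background. Mest was near background in the conventional clone, at 4.10 and 4.17 without and with the drug.

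The fourth comparison set the clones against each other with anti-CD3 alone. Cell cycle genes were called higher and receptor signalling genes lower in the unconventional clone (adjusted p = 0.0652 and adjusted p = 0.1180 with an estimated correlation). Lcp2, the adaptor SLP-76 of T cell receptor signalling, stood at 5.97 against 11.01 in the conventional clone (-5.05, SE 0.13, adjusted p = 5.2e-17). The integrin chains Itgae and Itgb7, which pair to bind E-cadherin, were higher by 3.90 (SE 0.09) and 3.95 (SE 0.14), and Itga1 was lower (-6.77, SE 0.12). Cd28 (-5.08) and Pdcd1 (-4.19), a co-stimulatory and an inhibitory receptor, were lower, and Cd200 was higher (6.11).

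In all, 8376 genes were called (42.0%), 4048 higher and 4328 lower in the unconventional clone, with 880 and 663 at least 2-fold. With arrays centred on the 75th percentile the split was 3405 higher and 6763 lower, and with median centring 59.9% of calls were higher. Arrays did not overlap for 7699 of all genes, against a chance share of 2.86%, and for 7118 of the called genes, picked on the same arrays. Besides Cd200, the largest positive differences were in Scin (7.62), an actin-severing protein, Brinp3 (6.73), the fatty acid desaturase Scd1 (6.55), the prostaglandin D synthase Hpgds (5.94), Dennd5a (5.74), Ppbp (5.74), the thiol reductase Ifi30 (5.70), Adh1 (5.66) and Tm4sf1 (5.55). Besides Itga1, the lowest were Car5b (-7.50), the opioid precursor Penk (-7.24), Ifitm3 (-6.64), the leukotriene receptor Cysltr1 (-6.60), Gimap3 (-6.47), Klra5 (-6.09), Csgalnact1 (-5.51), Ly6a2 (-5.51) and Sema3d (-5.40).

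Of 30 cell cycle genes, 28 were higher and 1 lower (29 and 1 adjusted over the list alone; camera adjusted p = 4.0e-19, median 1.43, and adjusted p = 0.0652 with an estimated correlation), such as Bub1 (2.52) and Rrm2 (2.02). AP-1 and MAPK feedback genes were lower in 20 of 26 cases and higher in 2 (21 and 2 adjusted over the list alone; camera adjusted p = 2.7e-07, and adjusted p = 0.0652 with an estimated correlation), with the ERK phosphatase Dusp6 at -4.00 and Spred1 at 3.46. Receptor signalling genes were lower in 15 of 30 and higher in 4 (15 and 5 adjusted over the list alone; camera adjusted p = 0.0030, and adjusted p = 0.1180 with an estimated correlation), including Ubash3a (-4.02) and Prkcq (-3.54). Interferon-stimulated genes were lower in 12 of 25 (12 adjusted over the list alone; camera adjusted p = 0.0068, and adjusted p = 0.1033 with an estimated correlation), TNF ligands in 4 of 11 (4 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.1033 with an estimated correlation) and glycolysis genes in 8 of 19 against 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.6680 with an estimated correlation). The glycolysis call was lost without conventional anti-CD3 replicate 4 (median -0.22). NK receptors were lower in 10 of 23 and higher in 5 (10 and 5 adjusted over the list alone; camera adjusted p = 0.0656), with Klri2 at -5.29 and Klrg1 at -4.06. Among the macrophage and dendritic markers, 6 of 20 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0934, median -0.02, mean 0.79). The higher ones included Cd74 (4.64), H2-Aa (4.59), H2-Ab1 (3.59) and H2-Eb1 (2.66), the class II genes and their chaperone, and Cd68 (1.44). The transcription factor Tbx21 was lower (-2.33), Cd8a (-2.19) and Cd8b1 (-2.08) were lower, and Ahr was higher (3.36).

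The fifth comparison set the clones against each other with anti-CD3 and cyclosporine A. Cell cycle genes stood further apart under the drug: 29 of 30 were higher in the unconventional clone and 1 lower (29 and 1 adjusted over the list alone; camera adjusted p = 1.7e-24, median 2.55, and adjusted p = 0.0563 with an estimated correlation), with Ccna2 at 4.73 (SE 0.16) and Bub1 at 4.48 (SE 0.14). Ifng (-2.62, SE 0.11) and Tnf (-1.81, SE 0.10) were lower there, and Il2 was not called (-0.10, adjusted p = 0.6698). Sterol synthesis genes were lower in 12 of 15 cases (12 adjusted over the list alone; camera adjusted p = 1.8e-04, and adjusted p = 0.6125 with an estimated correlation), and stress response genes in 16 of 23 against 4 higher (16 and 4 adjusted over the list alone; camera adjusted p = 2.6e-04, and adjusted p = 0.4792 with an estimated correlation).

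Of the 8821 called genes (44.2%), 4240 were higher and 4581 lower, with 1110 and 851 at least 2-fold. With arrays centred on the 75th percentile, 33.4% of calls were higher, against 48.1% as deposited. Arrays did not overlap for 8423 of all genes, against a chance share of 2.86%, and for 7711 of the called genes, picked on the same arrays. The largest positive differences were in Adh1 (8.09), Scin (7.59), Brinp3 (7.07), Scd1 (6.69) and Hpgds (6.43), and the lowest in Itga1 (-8.35), Car5b (-7.78), Penk (-7.47), Fgl2 (-7.25) and Sema3d (-6.77). AP-1 and MAPK feedback genes were lower in 18 of 26 and higher in 4 (19 and 4 adjusted over the list alone; camera adjusted p = 4.0e-05, and adjusted p = 0.1147 with an estimated correlation), and receptor signalling genes in 17 of 30 and higher in 3 (18 and 4 adjusted over the list alone; camera adjusted p = 2.3e-04, and adjusted p = 0.1147 with an estimated correlation), with Lcp2 at -6.40.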

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

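The tests on bright genes, on sets matched on level, on weakened responses and on markers of other cells were chosen only after the result was seen. How intervals over genes count against a bound was settled after first outcomes had been seen, and Itgax and Cd68, left out of the marker test at first, were put back then. For cyclosporine A in the conventional clone, 1 of the 35 splits of the arrays, the real one, gave as many as 6269 genes, and the highest other gave 1. The real split also gave the most for the unconventional clone (4970 genes, 1 of 35 splits, highest other 1). It did so for the clones with anti-CD3 alone (8376, 1 of 35, highest other 0) and with the drug (8821, 1 of 35, highest other 0). For the difference of effects the values were 3247, 1 of 100 drawn splits and highest other 1. Each other split mixes arrays of groups that differ, which widens its spread and keeps its count low. The low counts there do not exclude chance, and the replicates may be technical.

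The effect of cyclosporine A differed between the clones, by the test of the difference itself, for 3247 genes. Among the named ones it was lower in the unconventional clone for Pfpl (-5.38), Tm4sf1 (-4.16), Hsd11b1 (-3.34), Ubash3b (-3.32), Il17a (-3.32), Krt23 (-3.07), Il3 (-3.03), Csta3 (-2.93), Osgin1 (-2.89) and Gm5486 (-2.84). It was higher for Ccl9 (3.83), Lum (3.58), Tnfsf4 (3.38), Ambn (3.34), Acpp (3.31), Mest (3.26), AI504432 (3.18), Fat1 (3.17), Xylt1 (3.08) and Ifi205 (3.00). Some of these genes lay near background, as Mest did in the conventional clone (4.10 and 4.17 without and with the drug) and Tnfsf4 in the unconventional clone. AI504432 lay at 3.47 to 3.77 in the unconventional clone with the drug, a floor that limits a fall. In such cases a differing effect cannot be told apart from a differing level. The median difference was 1.13 for cell cycle genes, -0.99 for sterol synthesis, -0.38 for the stress response, -0.27 for receptor signalling, 0.30 for interferon-stimulated genes and 0.11 for T cell transcription factors. Of these 6 list calls, 0 held with an estimated correlation.

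Cell cycle genes fell less with cyclosporine A in the unconventional clone (adjusted p = 0.0950 with an estimated correlation). The median difference was 1.105 at its lowest and 1.136 at its highest over 4 other scalings. That was past the bound of 0.5 set beforehand, although the 95% interval over genes ran from 0.499 to 1.440. These scalings started from the deposited values, already normalized, so they cannot show what the first normalization did. A shift that depends on level is argued against, since 0 of 10000 sets of other genes matched on level in any group had a median as far from 0. The point values went against an equal weakening of every response, but it stays open. The share of effect kept was 0.561 larger for 8 cytokine genes than for 23 cell cycle genes (permutation p = 6.8e-04). The interval of this difference, 0.024 to 1.154, crossed the bound set for the test. For the 4 of these cytokine genes above a level of 6 with the drug in either clone, the share was 0.564 larger (exact permutation p = 0.0020). Both permutations treat genes as independent, while cell cycle genes had an estimated correlation of 0.290. A weakening of most responses that left cytokine genes aside stays open, because the share of the cell cycle genes differed by -0.113 from that of 875 genes in no list (-0.177 to -0.041, permutation p = 0.1490). The test on compression of bright genes could not decide. The 14 members under a level of 10 had a median of 0.704 and a wholly positive interval (0.294 to 1.478), against 1.13 over the whole list. That interval crossed the bound of 0.5, so compression stays open, above all for the brighter members. A difference between the clones in how division depends on the drug's target also stays open and was not tested.

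The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 and their chaperone Cd74, picked after their values were seen, were higher in the unconventional clone with anti-CD3 alone. Antigen-presenting cells among the cultures would bring their other transcripts. The other 25 macrophage, dendritic and B cell markers had a median difference of -0.075 (95% interval -0.149 to -0.001). That median pools markers of several cell types, so it cannot exclude a single type. Of these markers, 23 lay under a level of 6 in every group and 4 were lower, while Itgax (0.37, adjusted p = 0.0018) and Cd68 (1.44, adjusted p = 6.1e-09) were higher. The 23 dim markers thus gave no sign of such cells, but the brighter Itgax and Cd68 did not speak against them. Antigen-presenting cells stay open, as does expression by the clone itself, a hypothesis found on the same data.

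Single arrays stood apart from the other 3 of their group in 29 of 580 groups of the named genes (5.0%, against 5.4% over all genes), and chance gives about 1 in 20. The array with most of them, 7, was unconventional anti-CD3 replicate 1. The gap to the nearest array, as a share of the group's range, was there 0.833 for Ahr, 0.835 for Hmgcs1, 0.851 for Msmo1, 0.864 for Igf1, 0.883 for Klrd1, 0.896 for Sgce and 0.989 for Tnf, at 9.55 against 10.12 in the others. In the same group it was 0.953 for Csgalnact1, 0.886 for Penk and 0.889 for Trib3. With the drug, the unconventional clone gave 0.844 for AI504432, 0.852 for Car5b, 0.881 for Ccna2, 0.851 for Cd68, 0.848 for Gm5486, 0.883 for Il17f and 0.928 for Scin. The conventional clone gave 0.877 for Ccna2, 0.972 for H2-Aa, 0.830 for Il17a, 0.843 for Krt23 and 0.857 for Ubash3b with anti-CD3 alone. With the drug it gave 0.896 for Csn1s1, 0.945 for Il10, 0.905 for Il17f, 0.867 for Il1a, 0.896 for Itgb3, 0.894 for Trbv1 and 0.899 for Trib3.

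Probe sets with several or no gene symbol, which no comparison above used, numbered 7064, and cyclosporine A changed 1168 of them in the conventional and 737 in the unconventional clone.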

How the results depend on the processing

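None of the alternatives was chosen after the result was seen. No named gene or list that was called reversed its direction under any of them, but the near-even balance of higher and lower calls turned under several. The variance settings, the brightness filter and the replicate block leave a gene's change as it was, so they could not reverse it. Named genes were mostly picked for large changes, which makes a reversal unlikely elsewhere too. With anti-CD3 alone the calls between the clones were mostly higher after cyclic loess (3971 against 3483), after median centring (4418 against 2952), among the brighter genes (3853 against 2974) and at an adjusted p under 0.01 (3424 against 2947). The same held with the drug (4224 against 3796, 4374 against 3562, 3998 against 3258 and 3736 against 3219). Leaving out an array turned it for 3 of 16 arrays in either comparison. The balance also turned under 7 of 13 other settings in the conventional clone, 6 of 13 in the unconventional clone and 1 of 12 for the difference of effects. Requiring at least 2-fold changes gave 1009 genes for cyclosporine A in the conventional clone, 458 in the unconventional clone, 622 for the difference of effects, and 1543 and 1961 between the clones without and with the drug, by construction fewer. At an adjusted p under 0.01, the difference of effects was called for 2155 genes. The share of effect was 0.459 when picked at 1.5-fold, and the cause was not tested. The reverse share, the conventional clone's effect over that of the unconventional clone among genes picked in the latter, was 0.726, a different ratio by construction. With the correlation estimated 8 list calls held, and fry, which does not compare a list with other genes, made 93. Leaving out 1 array at a time gave 5869 to 6493, 4435 to 5105, 2931 to 3386, 7485 to 8581 and 8043 to 9258 genes in the same order, a share of 0.408 to 0.442, 37 to 43 lists and 559 to 567 called pairs of named gene and comparison. Of 648 such pairs, 598 stayed on their side of the threshold in all settings, 22 lost their call in some and 28 gained one. Of the 38 called lists, 34 kept their call apart from the other set tests. Centring on the 75th percentile gave 10168 genes between the clones with anti-CD3 alone and 11165 with the drug. Replicate numbers were shared by the groups, but same-numbered arrays did not deviate together throughout (lowest correlations -0.09, 0.05, -0.13 and 0.00 over 4 pairs of groups). The highest were 0.35, 0.22, 0.14 and 0.15, and 2 or 3 of 4 arrays were closest to their own number. An effect shared by replicate number is thus not excluded. With the replicate block, 6258, 4960, 3229, 8317 and 8778 genes were called, with 39 lists, 570 named pairs and a share of 0.425. It gave 5 named pairs a call, among them the difference of effects for Il2 (-0.68), and took 1 away. Signal over background limits what can be said of genes near a level of 4, whose changes are compressed.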

Other observations

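The gene families, single genes and chromosomes in this part were picked after their values were seen, and the tests on strongly changed genes and on brightness were chosen only after the result was seen. With anti-CD3 alone, all 8 measured Gimap genes, which encode GTPases of lymphocytes, were lower in the unconventional clone, by differences of -1.10 to -6.47, led by Gimap3 and Gimap4 (-5.20, SE 0.09). Peg10 and Sgce, a neighbouring pair of imprinted genes, were higher, at 10.51 against 5.08 (5.43, SE 0.17) and 9.35 against 4.48 (4.87, SE 0.17). Of 5 casein genes, which encode milk proteins, 4 were lower in the unconventional clone, but Csn1s2b (-0.34) lay near background in every group (3.29 to 3.63). Csn1s1 stood at 12.40 in the conventional clone with anti-CD3 alone and changed with cyclosporine A in both clones, by -3.46 and -3.56. Csn2 changed by -2.30 and -1.79, whereas Csn3 rose by 0.77 and 0.30. The called clone differences of these genes kept their sign under each of 4 other scalings.

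Genes of chromosomes 14 and 1, placed by the gene table of assembly GRCm38.p6, differed between the clones as blocks. Over 7321 genes with a mean level over 7, the median difference with anti-CD3 alone was 0.08. It was 0.55 over 264 genes of chromosome 14 and -0.33 over 428 genes of chromosome 1, against -0.05 to 0.18 on the other chromosomes. In 10 stretches of equal gene number, 9 of chromosome 14 lay above and 10 of chromosome 1 below the median of all genes.

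Without genes that differed at least 2-fold, chromosome 14 stayed 0.323 above all such genes (95% interval 0.259 to 0.390) and chromosome 1 at -0.351 (-0.387 to -0.307), which argues against a few strong genes as the source. Brightness is argued against too, since 0 of 10000 level-matched sets of other genes had a median as far for either chromosome. These sets treat genes as independent. A difference in chromosome number between the clones is a possible explanation that stayed open. Of dimmer genes, with means of 6 to 7 and not looked at by chromosome before, the 22 of chromosome 14 lay 0.214 above those of other chromosomes (95% interval 0.043 to 0.406), and the 37 of chromosome 1 at -0.003 (-0.097 to 0.135). The point values went for it on chromosome 14 and against it on chromosome 1. The interval of chromosome 14 crossed both bounds that were set. That of chromosome 1 just failed to reach the bound for the explanation but crossed the bound against it. Copy number was not measured here.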
